A study of Mus musculus with 4 samples.

How the data were processed

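Single-cell RNA sequencing was done on 4 mouse libraries, 1 each of melanoma cells and of CD8 T cells from co-cultures with wild-type B16-F10 or B16-OVA cells, 12 h after the start. Per the labels the libraries were made with the 10x Chromium 3' v3 kit and read on a NovaSeq. Per the submitters' processing notes, reads were converted with bcl2fastq and aligned to mm10 with Cell Ranger. The deposited matrices hold raw UMI counts per gene and barcode, with no normalisation, and name Cell Ranger 6.0.2 per the file headers. The settings for intronic reads, cell calling and filtering by the submitters are not given in the sources used here; the lowest barcode total was 831 UMIs in the wild-type melanoma library, 625 in the B16-OVA melanoma library and 500 in both T cell libraries. Gene positions and types came from GENCODE M21 on mm10 (GRCm38), matched by gene ID for 32235 genes. The bulk RNA sequencing of the same study was not part of the files and was left out.

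Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrial genes. These limits, the 25 gene lists, the 12 cell type marker sets, the fold and level limits, the rule for named genes and 18 of the alternative settings were chosen before the data were examined. In the wild-type melanoma library 872 barcodes fell under the UMI or gene limit and 2081 more over the mitochondrial limit; for B16-OVA melanoma these were 2925 and 1813, for T cells with wild-type cells 4279 and 1001, and for T cells with B16-OVA cells 3842 and 1613. Median depth over all barcodes was 13842, 6920.0, 11145 and 7348 UMIs in the same order. Scrublet, run in each library through scanpy 1.11.5 with its automatic threshold, called 0 doublets in every library, fewer than 0.5% of cells, so its calls were treated as not having worked and droplets with 2 cells remain in the data.

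Cells of the 4 libraries were clustered jointly in scanpy: log-normalised counts, 2000 variable genes, 30 principal components, 15 exact nearest neighbours and Leiden clustering at resolution 0.5 with igraph 0.11.9. Of 10 clusters, those with a higher median level of 10 T cell than of 9 melanoma markers were called T-like and the reverse melanoma-like, with at least 3 own markers detected. The 5 clusters with median UMI counts of 0.0883 to 0.251 relative to their libraries, and without an own marker among their 10 leading genes, were left unnamed. No other marker set led a cluster. Each class was clustered again with the same settings.

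For each comparison the raw counts of the kept cells of the library's own class were summed over cells and scaled to CPM, which add to 1000000 over all genes. Ratios are B16-OVA over wild-type, with an exact conditional binomial 95% interval. A gene was called higher or lower with a ratio of at least 2 and at least 50 CPM in the higher library. With 1 library per group no test and no p-value was possible, and intervals cover counting error only. The genes named are the 12 with the largest and the 12 with the smallest ratios at 50 CPM whose interval excludes 1. Unnamed predicted, mitochondrial, ribosomal protein and receptor segment genes were left out, as were genes more than 5 times as abundant in the other class. Here and in the lists, this 5-fold limit was judged only in the co-culture where the gene was higher. A ranked gene can therefore pass it in the co-culture where it was lower, as Id3 did in T cells. Up to 4 members of each list with the largest absolute log2 ratio, Epcam and Cd8a were added. List members were measured at 5 CPM in a library, and each list median was placed among 10000 random lists of the same size drawn from 20 bins of mean level. The lists cover early T cell receptor response, cytotoxic effectors, T cell cytokines, inhibitory receptors, naive and memory genes, costimulation, adhesion, actin and motility, calcium signalling, interferon response, MHC class I and class II, tumour immune ligands, tumour cytokines, pigmentation, mesenchymal genes, S phase, G2 and M phase, glycolysis, hypoxia, cholesterol synthesis, stress response, heat shock, p53 and oxidative phosphorylation.

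Shares of cells with a UMI and phase calls were computed after thinning each cell to the 10th percentile of depth of the pair, 5600 UMIs for T cells and 12700 for melanoma cells; shallower cells were left out. Phases came from scanpy's cell cycle score with the S phase and the G2 and M phase lists. Shares carry exact binomial intervals. The count comparison was tested on simulated data: all 100 of 100 genes with a true 4-fold difference were recovered in each comparison, 0 of 100 at 1.5-fold and 0 unchanged genes were called, and 95.2% and 96.2% of intervals held the true ratio for T and melanoma cells. The simulated counts were Poisson draws from the wild-type profile, without spread between cells or libraries. They check the calculation only and do not show how well the intervals cover real differences.

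The alternatives chosen beforehand were edgeR 4.0.16 TMM and DESeq2 1.42.0 median-ratio scaling, totals without mitochondrial and ribosomal protein genes, level floors of 10 and 200 CPM, a ratio of 1.5, a mean over cells, thinned counts, mitochondrial limits of 5% and 20%, at least 2500 UMIs and 1000 genes, whole libraries, doublet calls kept in, classes from each cell's marker UMIs, other thinning, resolution 1.0 and clustering without cell cycle genes. The 6 added after seeing the data left out the Ifng-leading cluster, the melanoma sub-cluster led by T cell genes, the 10% of cells with the highest Scrublet scores or cells over 2 times the median UMI count, added the low-UMI clusters, or clustered without genes apart between the libraries. Other tools were Python 3.11.15, anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, matplotlib 3.10.9 and R 4.3.3.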

Results

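Gene expression was measured by droplet single-cell RNA sequencing in 4 mouse libraries taken after 12 h of co-culture of melanoma cells with CD8 T cells, as the study's design text states. The T cells were OT-1 cells, which carry a transgenic T cell receptor for an ovalbumin peptide on MHC class I, and had been activated with CD3 and CD28 antibody beads. The melanoma cells were either wild-type B16-F10, a C57BL/6 mouse melanoma line, or B16-F10 transduced by lentivirus to make ovalbumin and a calcium sensor (B16-OVA). The cells were sorted by EpCAM antibody for cancer cells and by CD8 antibody for T cells, which gave 1 library in each of 4 groups. These were wild-type melanoma cells, B16-OVA melanoma cells, T cells from the wild-type co-culture and T cells from the B16-OVA co-culture. The labels of the melanoma libraries do not name the co-culture; it is taken from the design text. Total counts were 257329273 unique molecular identifiers (UMIs) over 18820 barcodes for wild-type melanoma, 150489386 over 14220 for B16-OVA melanoma, 223912180 over 19869 for T cells with wild-type cells, and 150319457 over 19692 for T cells with B16-OVA cells. With 1 library per group no difference has a replicate check, and every interval given here is a 95% interval that covers counting error only.

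Cells were called T-like or melanoma-like from clusters and fixed marker genes. After filtering, 13110 of 14589 cells were T-like in the T cell library of the wild-type co-culture and 13743 of 14237 in that of the B16-OVA co-culture. Melanoma-like cells numbered 10420 of 15867 in the wild-type melanoma library and 5905 of 9482 in the B16-OVA melanoma library. T-like cells were 6.74% of the wild-type melanoma library (6.36 to 7.14, exact binomial) and 14.9% of the B16-OVA melanoma library (14.2 to 15.6), shares that depend on the sort gates. Melanoma-like cells were 7 and 9 cells of the T cell libraries of the wild-type and B16-OVA co-cultures, or 0.0480% and 0.0632%. Cells of low UMI count that received no name made up 27.6% of the wild-type and 22.8% of the B16-OVA melanoma library, and 10.1% and 3.41% of the T cell libraries of the wild-type and B16-OVA co-cultures. The T-like class held 3 clusters, 2, 3 and 5, with 5884, 6737 and 1122 cells of the T cell library of the B16-OVA co-culture and 3951, 9152 and 7 of that of the wild-type co-culture, and cluster 5 was led by Xcl1, Ccl3, Ccl1, Ccl4 and Ifng. The melanoma-like class was held by different clusters, cluster 0 in the wild-type and cluster 9 in the B16-OVA library, and cluster 9 was led by Cxcl9, Ccl2, Isg15, Ifit3 and Ifit1. More than 10% mitochondrial UMIs were found in 12.7% of wild-type and 18.5% of B16-OVA melanoma barcodes, and in 6.95% and 12.6% of T cell barcodes from the wild-type and B16-OVA co-cultures.

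**Figure D1:**
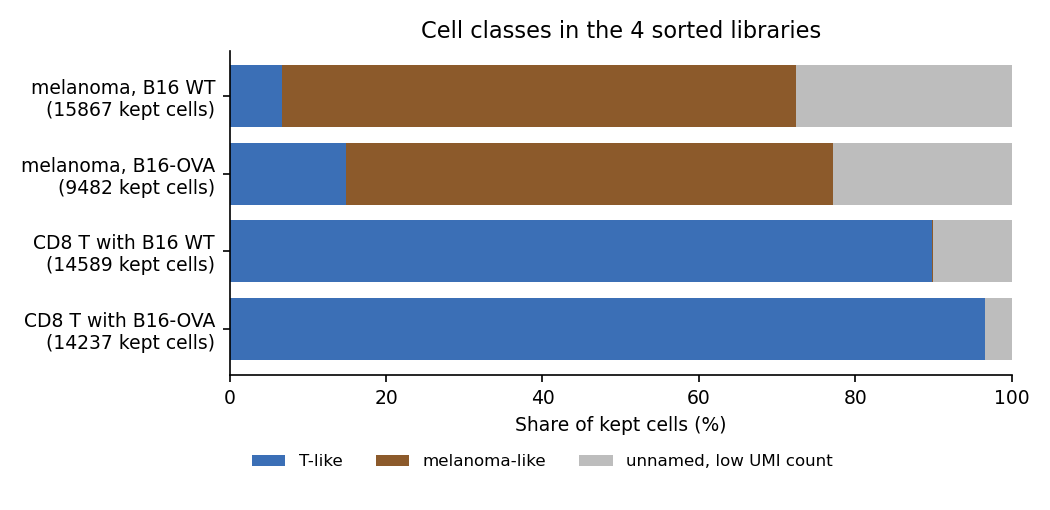
Share of kept cells (%) in each of the 4 libraries that were T-like, melanoma-like or unnamed because of a low UMI count. T-like cells made up 14.9% of the B16-OVA and 6.74% of the wild-type melanoma library.

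The sort markers were read as transcripts in every library, as counts scaled to the summed UMIs of the class (CPM). Cd8a, the alpha chain of CD8, stood at 382 CPM in T-like cells of the B16-OVA and 346 in those of the wild-type co-culture, and at 4.96 and 3.27 in melanoma-like cells of the B16-OVA and wild-type libraries. Epcam, the transcript of the antigen used to gate the cancer cells, was lower in the melanoma-like cells than in the T-like cells. It stood at 0.150 CPM (18 UMIs) and 0.0838 (19 UMIs) in melanoma-like cells of the B16-OVA and wild-type libraries, and at 8.60 and 7.84 in T-like cells of the B16-OVA and wild-type co-cultures. The transcript therefore gave no check of the EpCAM gate. No ovalbumin or calcium sensor sequence was among the counted genes, so neither transgene was read.

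T cells cultured with B16-OVA cells were compared with T cells cultured with wild-type cells, a pair that differs in the antigen that the T cells recognise and also in the transduced line, with its calcium sensor, that they were cultured with, which the design does not separate. The genes with the largest ratios belonged to the list of T cell cytokines and chemokines. Ccl1, a chemokine of activated T cells, was 66.7-fold (61.1 to 72.9) higher with B16-OVA cells, at 159.6 against 2.40 CPM. Xcl1, a chemokine that attracts cross-presenting dendritic cells, was 55.6-fold (53.3 to 57.9) higher, at 599 against 10.8 CPM, and the inflammatory chemokines Ccl3 and Ccl4 were 54.5-fold (51.8 to 57.4) and 21.1-fold (20.3 to 22) higher. Ifng, which encodes interferon gamma, was 9.81-fold (9.69 to 9.92) higher, at 1435 against 146 CPM and 204933 against 31408 UMIs. At a floor of 50 CPM, 2830 genes could be compared; 8 were at least 2-fold higher and 2 at least 2-fold lower with B16-OVA cells. The other genes on the higher side were Tnfrsf4, the costimulatory receptor OX40, at 2.67-fold (2.61 to 2.73), and Bcl2a1d (2.90-fold, at 50.3 CPM with B16-OVA cells) and Bcl2a1b (2.03-fold), survival genes of the Bcl-2 family that are near-identical copies and whose separate counts are uncertain. The lower genes were Id3, an inhibitor of E-protein transcription factors, which was 2.22-fold (2.14 to 2.30) lower at 27.1 against 60.1 CPM, and S100a4, a calcium-binding protein linked to cell motility, which was 2.16-fold (2.13 to 2.19) lower at 232 against 501 CPM.

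These genes lie, in the mm10 (GRCm38) build with GENCODE M21 coordinates, at chromosome 10, 118441046 to 118445892 for Ifng (ENSMUSG00000055170), chromosome 1, 164931644 to 164935527 for Xcl1 (ENSMUSG00000026573), chromosome 11, 82176657 to 82305690 for Ccl1 (ENSMUSG00000020702), chromosome 11, 83647844 to 83649355 for Ccl3 (ENSMUSG00000000982) and chromosome 11, 83662584 to 83664683 for Ccl4 (ENSMUSG00000018930). Each value is a count over the whole gene. Past the 2-fold genes, the next highest ratios were those of N4bp1 (1.94-fold), Tent5a (1.84), Klrk1, the activating receptor NKG2D (1.82), and Rgs1, a regulator of G protein signalling (1.75). On the lower side followed Egr1, an immediate early transcription factor (1.96-fold lower), Txnip (1.88), Ifitm1 (1.82), Epsti1 (1.78), S100a6 (1.73), Ifitm2 (1.72), Ms4a4b (1.71), Crip1 (1.69) and the histone genes Hist1h4a (1.69) and Hist1h4h (1.68), whose family shares sequence. Id3 was more abundant in melanoma-like cells, at 424 and 209 CPM in the B16-OVA and wild-type libraries, than in T cells. Across genes within this pair of libraries, the correlation of log levels was 0.982, and genes are not independent replicates.

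Most Ifng transcripts of the T cells with B16-OVA cells sat in a minority of cells. After each T-like cell was thinned to 5600 UMIs, 10.5% of T cells with B16-OVA cells (9.96 to 11.1; 1220 of 11606) and 0.920% with wild-type cells (0.761 to 1.10; 116 of 12604) held 10 or more Ifng UMIs. In the B16-OVA co-culture these cells held 81.9% of the thinned Ifng UMIs. Without thinning the shares were 14.9% and 5.61%. Thinning left out 2137 cells of the B16-OVA and 506 of the wild-type co-culture. When T-like cells were clustered alone, the sub-cluster with the most Ifng held 8.28% of the T cells with B16-OVA cells and 0.0534% with wild-type cells, and 5.98% and 0.0381% in a clustering that left out genes apart between the libraries and the cytokine list. With the cells of the joint cluster led by Xcl1, Ccl3, Ccl1, Ccl4 and Ifng removed, the ratio of Ccl1 was 7.68-fold (6.90 to 8.57), of Xcl1 6.61-fold (6.31 to 6.93), of Ccl3 6.32-fold (5.96 to 6.71), of Ccl4 3.30-fold (3.14 to 3.47) and of Ifng 2.55-fold (2.52 to 2.59). Then 3 genes, Xcl1, Ifng and Tnfrsf4, passed the 50 CPM and 2-fold limits on the higher side, and Id3 and S100a4 on the lower side. Ccl1, Ccl3, Ccl4 and Bcl2a1d (2.45-fold) stayed above 2-fold but fell under 50 CPM, and Bcl2a1b (1.70-fold) fell below 2-fold. The removal lowers the ratios of the genes that led the cluster by construction. The Ifng level outside that cluster was 370.3 against 145 CPM.

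**Figure D2:**
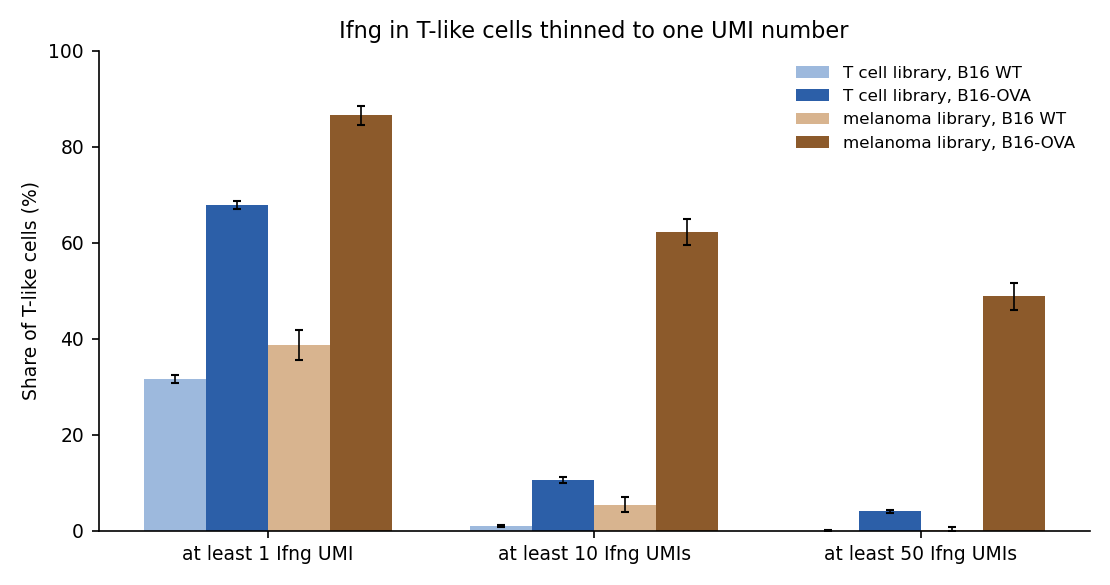
Share of T-like cells (%) with at least 1, 10 or 50 Ifng UMIs after thinning to 5600 UMIs, in the T cell and melanoma libraries of both co-cultures, with exact binomial 95% intervals. In the B16-OVA co-culture, 10 or more UMIs were held by 10.5% of T-like cells of the T cell library and 62.3% of those of the melanoma library.

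Counted as the share of cells with at least 1 UMI at the same depth, Ifng was seen in 67.9% of T cells with B16-OVA cells (67 to 68.7) and 31.6% with wild-type cells (30.8 to 32.4), and unthinned in 79.1% and 49.1%. Melanoma-like cells, thinned alike, gave a background of 24.6% and 1.01% in the B16-OVA and wild-type libraries. This background comes from the melanoma suspensions and includes the sub-cluster led by T cell genes, so it does not measure free RNA in the T cell libraries. Before thinning, the median depths were 9394 and 14766 UMIs for T-like cells and 19277 and 20256 for melanoma-like cells of the B16-OVA and wild-type co-cultures. The same shares with B16-OVA and wild-type cells were 22.6% and 2.96% for Ccl3 (background 9.83% and 0.145%), 20.1% and 5.16% for Ccl4 (6.96% and 0.165%), and 27.4% and 3.79% for Xcl1 (13.3% and 0.320%). Gzmb, the killing protease granzyme B, was seen in 99.8% and 99.7% (background 15.1% and 7.96%), and Prf1, the pore-forming protein perforin, in 6.77% and 2.60% (0.860% and 0.136%). Tnf was seen in 6.01% and 7.16% (background 0.584% and 0.194%), Il2 in 1.15% and 0.627% (0.499% and 0.126%), and Tnfrsf9, the receptor 4-1BB, in 62.1% and 48.5% (8.39% and 1.53%). The levels of Il2 lay further apart than its shares, at 4.20 and 0.627 UMIs per 100 thinned cells (background 1.22 and 0.126). Summed over all T-like cells, Il2 stood at 8.33 against 1.07 CPM, from 1190 and 230 UMIs. The inhibitory receptors Pdcd1, Lag3 and Havcr2 were seen in 12.2%, 14.1% and 12.1% with B16-OVA and 8.41%, 9.01% and 9.30% with wild-type cells, over backgrounds of 0.447%, 0.653% and 0.516% in the B16-OVA and 0.116%, 0.242% and 0.563% in the wild-type library. Without thinning, the shares with B16-OVA and wild-type cells were 30.9% and 6.88% for Ccl3, 27.5% and 11.3% for Ccl4, 36.6% and 7.64% for Xcl1, 99.8% and 99.8% for Gzmb, 10.1% and 6.37% for Prf1, 9.93% and 18% for Tnf, 1.75% and 1.74% for Il2 and 73.2% and 73.2% for Tnfrsf9. For the inhibitory receptors they were 20.8% and 21% for Pdcd1, 23.6% and 23% for Lag3 and 19.6% and 23% for Havcr2, so the order of Havcr2 and Pdcd1 turned and no order is read for these receptors. For Nr4a1 (4.96% and 7.0%, background 4.18% and 13.5%) and Tcf7 (7.49% and 12.8%, background 13.9% and 2.66%) a share lay at or below the background in 1 co-culture, and no order is read from them.

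Among the lists fixed in advance, the T cell cytokines and chemokines stood apart in the T cells: 9 of 13 measured members were at least 2-fold higher with B16-OVA cells and 0 lower. Their median log2 ratio of 3.29 lay at percentile 100 among 10000 random lists matched on size and mean level, which describes these libraries only. Csf2, which encodes GM-CSF, was 50.8-fold (42.3 to 61.5) higher. Without the Ifng-leading cluster 8 members were at least 2-fold higher, the median was 1.35 and the ratio of Csf2 5.30. Of the early T cell receptor response genes, 3 of 19 were at least 2-fold higher, namely Egr3 (4.82-fold, 4.29 to 5.43), Nr4a2 (2.04-fold, 1.90 to 2.19) and Tnfrsf4, 2 more, Irf4 (1.90) and Nr4a3 (1.85), at least 1.5-fold, and Egr1 was the member with the lowest ratio (0.509). The list median was 0.15 (percentile 99.98), and without the Ifng-leading cluster the ratio of Egr3 was 1.93 and that of Nr4a2 1.29. Of 15 cytotoxic effector genes 1 was at least 2-fold higher, Prf1 at 3.76-fold (3.51 to 4.02). Klrk1 (1.82), Serpinb6b (1.81) and Gzmc (1.71) were at least 1.5-fold higher, and the median was 0.21 (percentile 100). Without the Ifng-leading cluster the median was 0.04 and 0 of the genes were at least 2-fold higher. Prf1 then had a ratio of 1.73, Gzmc one of 1.48 and Serpinb6b one of 0.733. Serpinb6b was among the 10 leading genes of that cluster, which held 1122 cells with B16-OVA and 7 with wild-type cells. The removal therefore lowers its ratio by construction, and no change of direction is read from it.

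Inhibitory receptors and exhaustion factors had a median log2 ratio of 0.14 (percentile 99.6); 3 of 12 were at least 1.5-fold higher, Cd200 (2.36-fold, 2.23 to 2.50), Lag3 (1.73) and Pdcd1 (1.62), and 2 lower, Cd244a (0.520) and the transcription factor Tox (0.644). Without the Ifng-leading cluster the ratio of Cd200 was 1.67, of Lag3 1.499 and of Pdcd1 1.44, so Lag3 and Pdcd1 no longer reached 1.5-fold and Cd200 no longer 2-fold. Irf4, Nr4a3 and Tox lie outside the rule for named genes and were chosen after their values were seen. Of the naive and memory genes, Il7r, the interleukin-7 receptor, was 1.89-fold higher, Id3 and Tcf7, which mark memory potential, had ratios of 0.450 and 0.559, and the other members of the 12, such as Satb1 (1.33), were within 1.5-fold (median -0.09, percentile 4.46). Costimulatory receptors had a median of 0.14 (percentile 99.5), with Tnfrsf4 highest, Tnfrsf9 at 1.48 and Icos at 1.45, and Cd226 lowest at 0.559.

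The lists closest to T cell motility, which the study set out to follow, lay slightly lower with B16-OVA cells. Chemokine receptors, integrins and adhesion genes had a median log2 ratio of -0.21 over 19 members, at percentile 0. Members at least 1.5-fold lower included Ccr2, a receptor for monocyte chemoattractants (0.501, 21.5 against 42.9 CPM), and the integrin beta chain Itgb7 (0.600). Itgae had a ratio of 0.695. All 32 actin and motility genes were within 1.5-fold, with a median of -0.12 (percentile 0), and the furthest were Myh9, a non-muscle myosin heavy chain (0.794), Tmsb4x (0.809), Actb (0.814) and Rhoh (0.822). Of 22 calcium signalling genes, Atp2a3, a calcium pump of the endoplasmic reticulum, was more than 1.5-fold lower (0.646), Itpr1 had a ratio of 1.39, Ppp3ca 0.800 and Nfatc2 0.824, and the median was -0.11 (percentile 0.460). These medians are set against a median of 0.01 over all compared genes.

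The interferon response list had a median log2 ratio of 0.22 in T cells (percentile 100), but 10 of its 17 measured members were more than 5 times as abundant in melanoma-like cells of the same co-culture. Isg15, at a ratio of 3.39, was such a gene, with 6.15 CPM in T cells and 1189 in melanoma-like cells with B16-OVA cells. Iigp1 and Gbp5 had ratios of 1.83 and 1.60 and Irf1 0.687. Of the 3 measured MHC class II genes, Cd74 was 4.53-fold (4.15 to 4.93) higher in T cells and also more than 5 times as abundant in the B16-OVA melanoma-like cells, and H2-DMa and H2-Ab1 had ratios of 1.58 and 1.05 (median 0.66, percentile 99.9). All 42 S phase and all 52 G2 and M phase genes were within 1.5-fold, with medians of -0.06 and -0.11 (percentiles 0.830 and 0); Mki67 had a ratio of 0.822 and Top2a 0.821, while E2f8 (0.822) and Gas2l3 (0.760) were furthest. Phase scores placed 0.784% of T cells with B16-OVA cells (0.632 to 0.962) and 1.63% with wild-type cells (1.42 to 1.87) in G1, 12.1% and 10.3% in S, and 87.1% and 88% in G2 and M; unthinned G1 shares were 1.86% and 2.16%. Unthinned, S made up 2.90% and 10.8% and G2 and M 95.2% and 87.1%. At 8300 UMIs, S made up 7.84% and 12.1% and G2 and M 91.8% and 87%, so the order of both shares turned with depth and none is read. The calls come from relative gene scores, and free RNA stays open as a part of them.

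Of the stress genes in T cells, Atf3, a stress-induced transcription factor, was 2.25-fold (2.15 to 2.35) higher (1.97 without the Ifng-leading cluster), Asns, Ddit4 and Ddit3 had ratios of 1.39, 0.702 and 0.750, and the list median was -0.0042 (percentile 52). Of 17 MHC class I genes only H2-T23 passed 1.5-fold (1.65), in a gene family with shared sequence, and the median was 0.03 (percentile 67.7). Lists named for tumour cells had 1 immune ligand of 10, Ulbp1 (0.665), and 1 mesenchymal list gene of 5, Cdh1, which encodes E-cadherin (0.435), on the lower side, with medians of -0.07 and -0.05 (percentiles 15.6 and 34.9). Tumour cell cytokines (5 measured, median -0.10, percentile 16.8), glycolysis (16, -0.01, 34.2), hypoxia (11, -0.02, 40.3) and cholesterol synthesis (15, 0.03, 84) had no member beyond 1.5-fold. None passed it either in heat shock (6, 0.12, 97.2), p53 and apoptosis (13, -0.02, 36.2) and oxidative phosphorylation (17, 0.03, 55.8). Fewer than 3 melanocyte lineage and pigmentation genes reached 5 CPM in T cells, and the list was not measured there.

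B16-OVA melanoma cells were compared with wild-type melanoma cells. The pair differs both in the transduced genes and in carrying the antigen that the T cells recognise, and these were not separated by the design. The difference was far wider than in the T cells: of 3424 genes with 50 CPM, 383 were at least 2-fold higher and 297 at least 2-fold lower in B16-OVA cells. Across genes, the correlation of log levels was 0.661. Interferon response, antigen presentation and chemokine genes were higher, and cell cycle and pigmentation genes lower. Cxcl9, a T cell attracting chemokine induced by interferon gamma, stood at 13355 against 7.62 CPM (1752-fold, 1671 to 1838), and Ccl2, a monocyte chemoattractant, at 1793 against 1.01 CPM (1767-fold, 1553 to 2020.2). Ubd, a ubiquitin-like modifier, was 1126-fold (861 to 1504) higher, and C3, the central complement component, 929-fold (563 to 1660.4). Members of the interferon-inducible Ifi200 family had among the largest ratios: Ifi205 with 7262 UMIs against 1 (13682-fold, 2455 to 540489), Ifi207 (1417-fold, 828 to 2662), Ifi211 (989), Ifi204 (948) and Ifi203 (629), closely related genes whose counts are uncertain. Ly6c1, which resembles its neighbour Ly6c2, had 13277 UMIs against 6 (4169-fold, 1915 to 11363), and Slamf8 and Ifi44 had ratios of 648 and 602.

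On the lower side in B16-OVA cells, Gsta4, a glutathione S-transferase, was 55.2-fold (46.8 to 65.7) lower at 1.16 against 64.3 CPM and Met, the receptor of hepatocyte growth factor, 15.8-fold (15.2 to 16.5) lower at 19.98 against 316 CPM. Lgals3, which encodes galectin-3, was 18.6-fold (17.8 to 19.5) lower, Ptgds, a prostaglandin D synthase, 9.21-fold (9.06 to 9.36) lower at 128 against 1178 CPM, and Lmo1, Pla2g2e, Vill, Nckap5l and Tspan10 had ratios of 0.0577, 0.0595, 0.0802, 0.0959 and 0.111. The DNA replication genes Tk1 (thymidine kinase) and Uhrf1 and the histone gene Hist1h2ae were 8.65, 8.12 and 8.53-fold lower. Cxcl9 (ENSMUSG00000029417) lies at chromosome 5, 92321347 to 92328079, Ccl2 (ENSMUSG00000035385) at chromosome 11, 82035571 to 82037453, Gsta4 (ENSMUSG00000032348) at chromosome 9, 78182774 to 78209349 and Met (ENSMUSG00000009376) at chromosome 6, 17463800 to 17573980 of mm10 (GRCm38). A melanoma sub-cluster led by T cell genes held 2.85% of melanoma-like cells of the B16-OVA library and 3.71% of the wild-type library. Without the sub-cluster led by T cell genes the ratio of Lgals3 was 0.0192 in place of 0.0537, and that of Ly6c1 12136-fold (3359 to 100225).

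**Figure D3:**
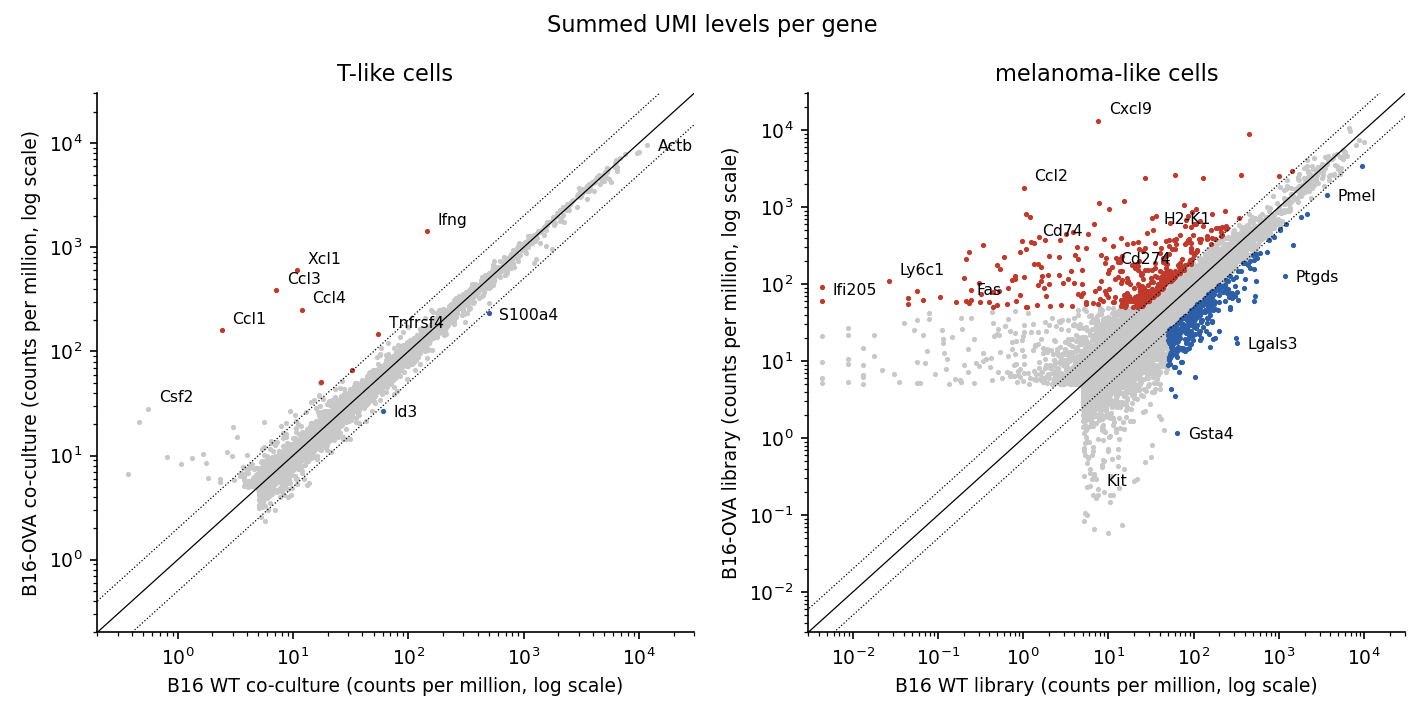
Level of each gene in CPM (log axes) in the B16-OVA against the wild-type co-culture, for T-like and melanoma-like cells. Red and blue points are genes at least 2-fold higher or lower with a level of 50 or more, and dotted lines mark 2-fold. Genes under 5 CPM in both libraries, or without a UMI in 1 library, are not drawn. T-like cells had 8 higher and 2 lower genes, melanoma-like cells 383 and 297.

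Interferon response and antigen presentation genes were higher in B16-OVA cells together. All 25 of 25 measured interferon response genes were at least 2-fold higher, with a median log2 ratio of 4.48 (22.3-fold, percentile 100); examples were Gbp5 (286-fold, 249.8 to 329.9), Irf7 (154-fold, 132 to 180.1), a transcription factor of the interferon response, and Usp18 (136-fold, 121 to 153). Of 16 MHC class I genes 14 were at least 2-fold higher (median 2.92, percentile 100), among them the peptide transporter subunit Tap2 (31-fold, 29.2 to 32.9), the immunoproteasome subunit Psmb9 (16-fold, 15.4 to 16.6) and the class I heavy chain genes H2-K1 (14.8-fold, 14.5 to 15.2) and H2-T23 (49.2), which belong to a family with shared sequence. All 7 of 7 MHC class II genes were higher (median 7.14, percentile 100), such as the invariant chain gene Cd74 (284-fold, 252 to 319.9, 355 against 1.25 CPM), H2-Aa (358), H2-Eb1 (199) and H2-Ab1 (141). Of 12 immune ligands of tumour cells 8 were at least 2-fold higher and 3 lower (median 2.64, percentile 100). The death receptor gene Fas was 284-fold (214 to 385) higher, Vcam1 73.6-fold (47.8 to 119), and Cd274, which encodes the checkpoint ligand PD-L1, 14.9-fold (14.2 to 15.5), at 153 against 10.3 CPM, while Lgals3, Raet1d (0.141) and Cd276 (0.196) were lower, of which Raet1d and Cd276 were chosen after their values were seen. Of 12 tumour cell cytokines and chemokines 10 were higher (median 4.25, percentile 100), with Ccl5 at 146-fold (139 to 153) and Cx3cl1 at 46.8-fold (39.5 to 55.9) beside Ccl2 and Cxcl9, and Tgfb1, chosen after its value was seen, at 0.530.

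Cell cycle and pigment cell genes were lower in B16-OVA cells. Of 42 S phase genes 37 were at least 2-fold lower and none higher, with a median log2 ratio of -2.09 (percentile 0); Cdc6, Exo1 and Mcm2, which act in DNA replication and repair, were 9.17, 7.26 and 6.71-fold lower. Of 52 G2 and M phase genes 43 were at least 2-fold lower (median -1.57, percentile 0), among them the mitotic genes Kif23 (7.13-fold, 6.69 to 7.61), Ncapd2 (5.67-fold), Kif11 (5.48) and Cdca2 (5.23). Phase scores at 12700 UMIs per cell placed 66.4% of B16-OVA cells (65.1 to 67.7) and 9.93% of wild-type cells (9.33 to 10.5) in G1, 18.6% and 39.6% in S, and 15% and 50.5% in G2 and M. Phase calls rest on relative scores, free RNA stays open as a part of them, and no rate of division is read from them. Thinning left out 709 and 910 cells, and unthinned G1 shares were 68.8% and 12.6%. When melanoma-like cells were clustered alone, the sub-clusters, apart from the one led by T cell genes, split almost wholly by library, so their shares do not compare cycling between the libraries. The sub-cluster with the highest level of Mki67, a proliferation marker, held 3242 wild-type cells and 1 B16-OVA cell, at 483 CPM. Among the sub-clusters that held only B16-OVA cells the highest Mki67 level was 303 CPM, in 286 cells or 4.84% of the B16-OVA cells, with Top2a at 611 CPM against 804 in the wild-type one. Of 17 melanocyte lineage and pigmentation genes 12 were at least 2-fold lower and none higher (median -1.39, percentile 0). The growth factor receptor Kit was 24.6-fold (17.6 to 35.4) lower, Rab27a and Mlph, which act in melanosome transport, 4.87 and 3.89-fold, and Mitf, the lineage transcription factor of melanocytes, 3.78-fold (3.68 to 3.89).

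**Figure D4:**
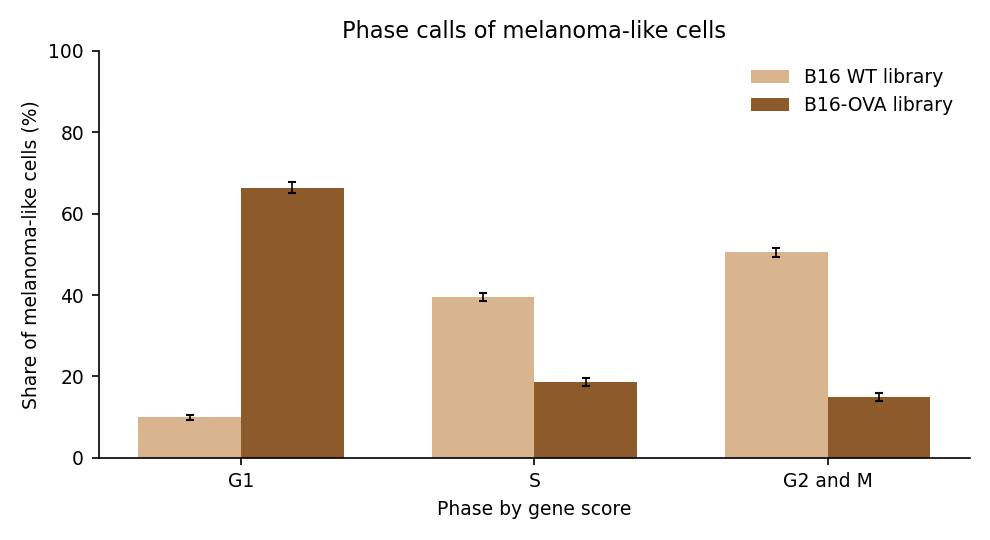
Share of melanoma-like cells (%) placed in G1, S or G2 and M by gene scores after thinning to 12700 UMIs, in the wild-type and B16-OVA libraries, with exact binomial 95% intervals. G1 calls made up 66.4% of B16-OVA and 9.93% of wild-type cells.

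Several other lists held members apart in both directions in the melanoma cells. Of 11 dedifferentiation and mesenchymal genes 7 were at least 2-fold higher and 1 lower (median 1.42, percentile 100): the matrix gene Fn1 was 16.2-fold (15.8 to 16.7) higher, Snai2 5.07-fold and Jun 4.49-fold, and the integrin chain Itga5 was 4.50-fold lower. In the p53 and apoptosis list 7 of 14 were at least 2-fold higher (median 0.86, percentile 100), among them the cell cycle inhibitor Cdkn1a (5.55-fold, 5.47 to 5.63, 598 against 108 CPM), Btg2 (7.59) and Gadd45a (4.33). Of 27 actin and motility genes Fyb (2.77), Vim (2.52) and Arpc1b (2.01) passed 2-fold, Msn had 1.68, and the median was 0.04 (percentile 88.6), or 0.37 without the sub-cluster led by T cell genes. Calcium signalling had 5 of 19 genes more than 1.5-fold lower, namely Plcg1 (0.527), Nfatc2 (0.533), Calm2 (0.589) and Stim2 (0.632) beside Atp2a2 (0.652), which was chosen after its value was seen, and a median of -0.23 (percentile 18.4). In cholesterol synthesis Insig1 (0.399) and Dhcr7 (0.431) were lower (median -0.28, percentile 12.6), and in glycolysis Pfkp (2.18) and Hk2 (2.0) were higher and Slc16a3 (0.568) and Eno1 (0.601) lower (median -0.21, percentile 25.8). Of the stress response genes Atf3 (2.52) and Ddit4 (2.05) passed 2-fold and Xbp1 had 1.69 (median 0.14, percentile 88.7). Hypoxia (11 measured, median -0.03, percentile 57.1), heat shock (6, -0.34, 14.8) and oxidative phosphorylation (17, -0.17, 36.1) had no member beyond 2-fold; Bnip3 (1.91), Hsph1 (0.665) and Cox6c (0.701) were furthest.

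Lists of T cell genes were counted in the melanoma-like cells too. T cell cytokines and chemokines had 8 of 10 members at least 2-fold higher in B16-OVA cells (median 6.62, percentile 100). Of these, Ccl3 (104 against 0.304 CPM), Xcl1 (128 against 0.812 CPM) and Ccl4 (58.6 against 0.401 CPM) were each more abundant in the T-like cells of the same co-culture. Of the cytotoxic effector genes 4 of 9 were higher (median 0.90, percentile 99.9), the death ligand Tnfsf10 (37.6), Serpinb6b (6.79), the proteoglycan Srgn (2.56) and Serpinb9, an inhibitor of granzyme B (4.05). Of these 9, 5 were more than 5 times as abundant in T cells, namely Srgn and, chosen after their values were seen, Gzma, Gzmb, Gzmc and Nkg7, and without the sub-cluster led by T cell genes 7 were at least 2-fold higher and the median was 1.39. The early T cell receptor list had 6 higher and 5 lower of 15 (median 0.61, percentile 99.9), with Tnfaip3 at 7.55; the lower ones were Egr1 (0.0904) and, chosen after their values were seen, Dusp2 (0.187), Nr4a1 (0.303), Fos (0.402) and Ier2 (0.486). Of 4 naive and memory genes Tcf7 (5.99) and Id3 (2.03-fold, 2.0 to 2.05) were higher (median 0.71, percentile 97.2), and of 3 costimulatory genes 2, Tnfrsf4 and Tnfrsf9 (median 2.50, percentile 99.5), of which 2 were more than 5 times as abundant in T cells. The costimulatory median was 1.69 without the sub-cluster led by T cell genes. Chemokine receptors, integrins and adhesion genes had 2 higher and 1 lower of 6 (median 0.45, percentile 91.7), Icam2 (8.60), Icam1 (6.11) and Itga4 (0.335). Fewer than 3 inhibitory receptor genes reached 5 CPM, and that list was not measured in melanoma-like cells. Among all genes past 2-fold, 4 were more than 5 times as abundant in T cells in the co-culture where the gene was higher in melanoma-like cells. These were not ranked: S100a6 (2.65), Tuba4a (0.107), Tagln2 (7.18) and Crip1 (0.214, chosen after its value was seen). Genes past that limit only in the other co-culture were not counted here. Without the sub-cluster led by T cell genes the ratio was 11.1 for Tnfrsf9 (5.65 with it), 74.7 for Tnfsf10, 32.7 for Icam1, 2.68 for Serpinb6b (6.79 with it), 5.39 for S100a6, 24.4 for Tagln2, 0.0575 for Tuba4a, 4.11 for Srgn and 3.22 for Tnfrsf4 (6.28 with it).

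**Figure D5:**
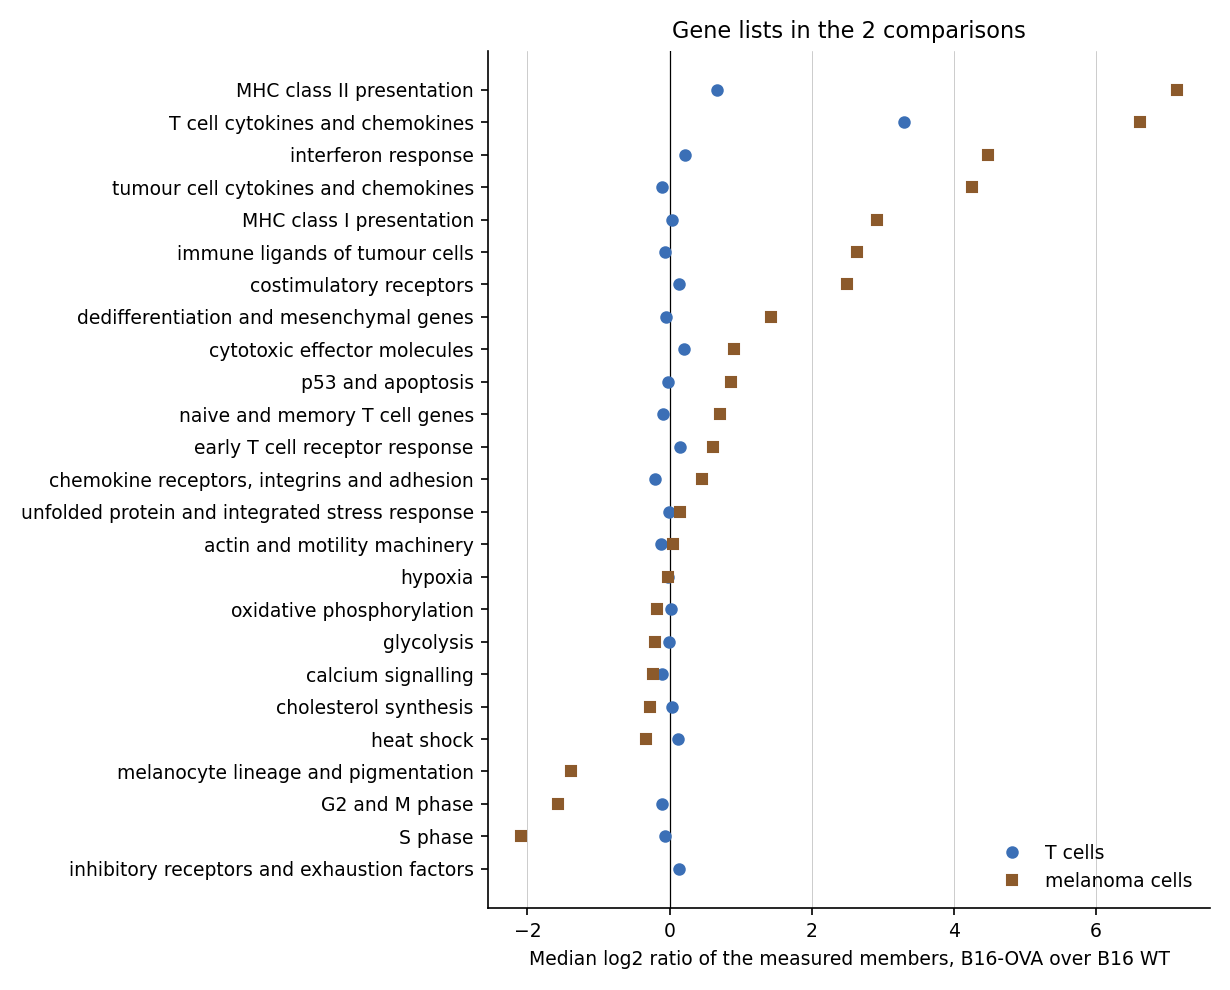
Median log2 ratio (B16-OVA over wild-type co-culture) of the measured members of each gene list, as circles for T-like and squares for melanoma-like cells; lists with fewer than 3 measured members in a class have no point there. The interferon response list stood at 4.48 in melanoma-like cells and 0.22 in T-like cells.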

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

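Of the tests in this part, those of droplets with both cell types and of free RNA for the T-like cells, and that of Ifng UMIs outside the sub-cluster led by T cell genes, were chosen only after the result was seen. The T-like cells that were sorted with the melanoma cells were not part of either comparison and are described here because their share in the Ifng-leading cluster lay above that of the control library.

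In the B16-OVA melanoma library 64.9% of T-like cells (62.4 to 67.4; 916 of 1411) lay in the cluster led by Xcl1, Ccl3, Ccl1, Ccl4 and Ifng, against 0.467% (0.152 to 1.09) in the wild-type melanoma library and 8.16% in the T cell library of the B16-OVA co-culture. Droplets holding a T cell and a melanoma cell are argued against as the main source. Of the 997 droplets of that library, of any class, with at least 10 T marker and 10 Ifng UMIs, 12% (10.1 to 14.2; 120) had 20% or more of the melanoma marker share of melanoma-like cells. Without such mixed droplets, 10 Ifng UMIs were reached by 62.6% of droplets with 10 T marker UMIs, against 15.1% in the T cell library. Free RNA in the suspension, which would enter all droplets, is argued against as the whole source because melanoma-like cells of that library held 6.25 Ifng UMIs per cell and all its T-like cells 184, a ratio of 0.0340 (0.0337 to 0.0344). The Epcam ratio inside over outside the cluster was 1.16 (0.969 to 1.38) in the T cell library. That library was sorted by CD8 and may lack cells that passed the EpCAM gate, so this ratio does not decide. In the co-sorted T-like cells, Epcam stood at 8.30 CPM inside and 6.34 outside the cluster. Their level over that of the T cell library was 0.898 (0.745 to 1.075), a value chosen after the result was seen. No higher Epcam transcript level of the co-sorted T-like cells as a whole was seen. A candidate explanation, which was not tested, is that T cells that had recognised the antigen stayed attached to cancer cells and passed the EpCAM gate with them. At 5600 UMIs, 62.3% of T-like cells of the B16-OVA melanoma library and 10.5% of its T cell library held 10 or more Ifng UMIs. In the wild-type co-culture, without the antigen, these shares were 5.31% and 0.920%. By this measure an excess in the melanoma library was seen in both co-cultures. Its size differed between genes. The level over that of the T cell library was 10.5 with B16-OVA and 2.32 with wild-type cells for Ifng. For Il2 these ratios were 18.8 and 1.18 (0.637 to 2.03), and for Ccl1, in the other order, 10.7 and 23. Whether the antigen changed the excess was not tested. Conjugates sorted as 1 event that came apart and EpCAM protein taken up from cancer cells were not tested and stay open.

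Melanoma-like cells of the B16-OVA library held Ifng UMIs at 307 CPM, and 84.8% of them lay in the sub-cluster led by T cell genes, where the level was 6309 CPM against 48.6 outside. The median depth was 29614 UMIs inside and 19138 outside that sub-cluster. A small number of droplets with a T cell and a melanoma cell could hold most of these UMIs, since the 5% of melanoma-like cells with the most Ifng held 87.5% of them (87.2 to 87.9; 296 of 5905 cells). Free RNA from activated T cells may add to them, because Ccl3, Ccl4, Xcl1 and Prf1 per Ifng UMI were within 2-fold of the co-sorted Ifng-leading cluster for 4 of 4 genes, and for 4 of 4 genes outside the sub-cluster as well, a ratio that mixed droplets keep too. Whether melanoma cells make any Ifng was not tested.

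Id3 had opposite directions in the 2 comparisons. The ratio of B16-OVA over wild-type was 0.450 in T cells and 2.03 in melanoma cells; the difference was not tested.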

How the results depend on the processing

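Of the settings named in this part, the removal of the Ifng-leading cluster, the removal of the highest Scrublet scores and the clustering without genes apart between the libraries were chosen only after the results were seen. No paired analysis was possible because each group has 1 library. The ratio of each gene picked by the rule for named genes was recomputed under 9 planned and 4 added settings. Other genes at least 2-fold apart were not recomputed one by one. The doublet calls, level floors, ratio of 1.5, classes from each cell's markers, other thinning and clustering alternatives were not among these settings. For the named genes at least 2-fold apart, 0 of 1365 values turned direction and 1344 stayed at least 2-fold. Most of these genes were picked for their large ratios, so a change of direction was unlikely from the outset. Serpinb6b, 1.81-fold in T cells, had a ratio of 0.733 without the Ifng-leading cluster. It was a leading gene of that cluster, so the removal lowers its ratio by construction. Gene counts stayed within 1.5 times the reported count in 51 of 64 cases. With TMM scaling all 8 higher and 2 lower T cell genes were shared; with totals without mitochondrial and ribosomal protein genes 429 melanoma genes were higher and 415 lower, of which 368 and 297 were shared. Scrublet called 0 doublets, so keeping its calls says nothing about doublets.

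In T cells, 33 genes were at least 2-fold higher and 7 lower at a floor of 10 CPM, 4 and 1 at 200 CPM, and 18 and 19 at a ratio of 1.5. Without the Ifng-leading cluster 3 were higher at the floor of 50 CPM. Ccl1, Ccl3, Ccl4 and Bcl2a1d then fell under that floor but stayed above 2-fold. In melanoma cells the counts of higher and lower genes were 768 and 772 at 10 CPM, 120 and 58 at 200 CPM, and 588 and 657 at a ratio of 1.5. A lower floor or ratio admits more genes by construction. T-like cells made up 8.61% of the wild-type and 17.5% of the B16-OVA melanoma library with at least 2500 UMIs and 1000 genes, 5.80% and 15.8% with classes from each cell's markers, and 14.1% of the B16-OVA library with a mitochondrial limit of 20%. T cells in G1 with B16-OVA and wild-type cells were 0.399% and 0.890% at the 25th percentile of depth, and 1.86% and 2.16% unthinned. S shares turned order, from 12.1% and 10.3% to 7.84% and 12.1% at the 25th percentile and 2.90% and 10.8% unthinned. G1 shares were 1.04% with B16-OVA cells at 20% mitochondrial UMIs and 2.02% with wild-type cells without the highest Scrublet scores. In B16-OVA melanoma cells G1 was 68.8% unthinned, 67.8% at 20% mitochondrial UMIs and 69.9% without the highest Scrublet scores. For wild-type melanoma cells it was 8.96% at the 25th percentile, 12.6% unthinned, 10.7% and 11.8% at mitochondrial limits of 5% and 20%, and 10.97% without the highest scores. T cells with an Ifng UMI were 75.6% and 38.9% at the 25th percentile, and 79.1% and 49.1% unthinned. The sub-cluster with the most Ifng held 5.98% of T cells with B16-OVA cells when genes apart between the libraries were left out, against 8.28% with them. Most melanoma sub-clusters split by library, so how the share of the one with the most Mki67 moved with the clustering is not read. Apart from the floors and the ratio, which act by construction, the cause was not tested. Depth limits the shares of cells with a UMI, and 6 or fewer UMIs stood behind the wild-type levels of Ifi205 and Ly6c1.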

Other observations

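T-like cells that had been sorted with the melanoma cells, 1411 from the B16-OVA and 1070 from the wild-type library, were compared in the same way, a comparison chosen only after the other results were seen. Cytokine genes were higher in those sorted with B16-OVA cells. Ifng was 44.3-fold (42.9 to 45.8) higher, the chemokine Ccl3 204-fold (182 to 230.2), Xcl1 116-fold (107 to 125) and Csf2, which encodes GM-CSF, 198-fold (139 to 294). Prf1, the pore-forming protein of killer cells, was 7.13-fold (6.20 to 8.22) higher, the transcription factor Egr3 21.2-fold (14.4 to 32.7), and the inhibitory receptors Lag3 and Pdcd1 4.77-fold (3.97 to 5.77) and 3.23-fold (2.76 to 3.80). Without the Ifng-leading cluster, which was led by several of these genes, 495 and 1065 cells were left. The ratios were then 1.21 (1.15 to 1.28) for Ifng, 3.71 (3.13 to 4.40) for Ccl3, 1.60 (1.41 to 1.81) for Xcl1 and 2.25 (1.29 to 3.93) for Csf2. They were 1.69 (1.37 to 2.08) for Prf1, 3.13 (1.83 to 5.44) for Egr3, 1.81 (1.39 to 2.35) for Lag3 and 1.25 (0.972 to 1.59) for Pdcd1. Each was lower than with all cells. The direction turned for Ccl1, from 31.1 to 0.394 (0.315 to 0.489), for Nr4a2, from 4.67 to 0.711 (0.510 to 0.978), and for Gzmc, from 1.13 to 0.574 (0.534 to 0.616). It also turned, with intervals that exclude 1 both with and without the cluster, for Slc2a3 (from 1.54 to 0.764) and Vim (from 0.723 to 1.06). Nt5e went from 0.922 (0.707 to 1.21), an interval that holds 1, to 1.95 (1.45 to 2.63). The removal took 916 T-like cells of the B16-OVA and 5 of the wild-type library. Ccl1, Ccl3, Ccl4, Xcl1, Ifng and Csf2 were leading genes of the cluster, so their ratios fall by construction. How much of a difference lay in the cluster is therefore not read from the removal. No lower Ccl1 level and no change of direction of another gene in the remaining cells is read from it either. With all cells, 68 of 2861 genes were at least 2-fold higher and 32 lower, against 15 and 10 of 2836 without the cluster. Of the 68 and 32, 8 and 7 were more than 5 times as abundant in melanoma-like cells. Melanoma markers made up 0.0563% of the UMIs of these T-like cells in the B16-OVA and 0.174% in the wild-type library. Of 14 pigmentation genes 11 were at least 2-fold lower, with 13 more than 5 times as abundant in melanoma-like cells, and of 25 interferon response genes 10 were higher, with 18 that abundant there, so neither list is read as a change in T cells. With all cells, all 8 genes that were higher in the T cell libraries were shared, and 1 of the 2 lower genes. Without the cluster, Ccl3, Ccl4 (2.79) and Tnfrsf4 (2.20) of the 8 stayed at least 2-fold higher. Bcl2a1d (1.98), Xcl1, Bcl2a1b (1.54) and Ifng fell below 2-fold, and Ccl1 below 1. Both sets of cells came from the same co-cultures, so the overlap is not an independent check.

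Among lists in these co-sorted cells, 15 of 18 cytokine genes, 9 of 20 early T cell receptor genes and 5 of 11 costimulatory receptors were at least 2-fold higher, with median ratios of 30.7, 1.28 and 1.49, which were 1.39, 0.980 and 1.17 without the Ifng-leading cluster. Of chemokine receptors, integrins and adhesion genes 8 of 19 were at least 2-fold lower and 0 higher, with a median ratio of 0.555; Ccr2 and Itgb7 had ratios of 0.299 and 0.328. Without the cluster 0 were 2-fold lower, the median ratio was 0.901 and those of Ccr2 and Itgb7 0.794 and 0.679. No actin and motility, S phase or G2 and M phase gene passed 2-fold. Their median ratios were 0.853, 0.827 and 0.853 (percentiles 0.01, 0 and 0), and 0.996, 0.977 and 1.01 without the cluster. Within the B16-OVA co-culture, the level in T-like cells of the melanoma library over that of the T cell library was 10.5 for Ifng, 13.8 for Ccl3, 11.4 for Xcl1, 10.7 for Ccl1, 18.8 for Il2, 6.74 for Prf1 and 1.21 for Gzmb. In the wild-type co-culture the same ratios were 2.32 for Ifng, 3.69 for Ccl3, 5.47 for Xcl1, 23 for Ccl1, 1.18 (0.637 to 2.03) for Il2, 3.55 for Prf1 and 0.957 for Gzmb.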
